A study of Homo sapiens with 8 samples.

How the data were processed

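RNA was measured in BJ cells, a skin fibroblast line, in a derivative that the labels call BJ-HRAS. There were 2 WT clones (15 and 54) and 2 SNORA13 knockout (KO) clones (66 and 69), which the labels call independent. Each clone was sampled without and with (Z)-4-hydroxytamoxifen (4-OHT) at 100 nM for 7 days, giving 8 libraries in 4 groups of 2. Per the labels' protocols, RNA was isolated with a column kit that keeps small RNA, treated with DNase and made into libraries with a stranded total RNA kit. Such libraries hold transcripts without a poly(A) tail, among them replication-dependent histone messages, and small nucleolar RNAs (snoRNAs) as far as their short fragments survive. Per the submitters' processing notes, STAR, featureCounts and edgeR were used with the GRCh38 build. Their versions, settings, strand setting and roles are not given in the sources used here.

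The authors deposited 1 table of 58870 genes with a value column per library. Its values are RPKM, reads per kilobase of transcript, scaled to the library total, although it is named for counts. Per the file headers, columns carry the clone number alone or with a minus sign. The sign was read as 4-OHT negative and the bare number as 4-OHT positive, a reading of the names that no label spells out. Of the values above 0 in genes with a listed transcript length in GENCODE release 29, 100.0% became whole reads, within 0.1 read, when multiplied by that length and by 1 library total. For 6676 genes the length was inferred from the steps between their own values. The library totals found in this way were 22.1 to 24.9 M reads, and the recovered reads summed to within 0.2% of them. The 45 duplicate rows of the pseudoautosomal Y copies were left out. At these totals 1 read in a transcript of 1 kb is worth 0.0401 to 0.0453 RPKM.

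The fixed plan named edgeR's count test, which was not used because the deposited unit is RPKM; limma took its place. RPKM values were divided by trimmed-mean (TMM) factors computed from the recovered reads, which lay between 0.9398 and 1.035. Genes were kept when at least 2 libraries reached 10 reads at the median library size (a CPM of 0.425) and the total reached 15 reads, leaving 16544 genes. On log2(RPKM + 0.1), limma 3.58.1 in R 4.3.3 fitted 4 group means over all 8 libraries (4 residual degrees of freedom), with an intensity trend and robust moderation. All p-values are two-sided and Benjamini-Hochberg adjusted over the genes tested, with 0.05 as threshold. Fold changes are on this log2(value + 0.1) scale, which understates the change of low genes. Means ± SD are TMM-scaled RPKM over the 2 clones of a group. SNORA13, CDKN2A and IL6 did not pass the filter and were described by their reads. The contrasts were the 4-OHT response in WT, the same in KO, KO minus WT without and with 4-OHT, and the difference of the responses (KO response minus WT response, the interaction). With groups of 2 clones, p-values measure the spread between clones, and a KO minus WT difference holds whatever else sets those clones apart.

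Lists of genes were fixed from textbook knowledge before the data were examined: p53 targets, secreted factors of senescent fibroblasts (SASP), RAS-MAPK output, DNA replication and G1/S, mitotic genes, replication-dependent histones, ribosomal proteins of either subunit, ribosome biogenesis factors, snoRNA host genes, H/ACA and C/D snoRNAs, extracellular matrix, contractile and myofibroblast genes, cholesterol synthesis, the integrated stress response, interferon-stimulated genes, glycolysis and hypoxia, nuclear-encoded oxidative phosphorylation, mitochondrially encoded messages, lysosome, the genes around SNORA13 on 5q22, and markers of fibroblasts, epithelial cells, endothelial cells, immune cells, and melanocytes or neural cells. Of the 27 lists, 24 had at least 5 tested members. The endothelial, immune and melanocyte or neural lists had 3, 4 and 2, and were not tested. Lists were tested with camera (preset correlation 0.01, adjusted over the 24 lists of a contrast), which compares a list with the other genes. No list was called in any of the 5 contrasts when the correlation between members was estimated from the 8 libraries, so that p is given in the text with each list called. This variant rests on the 4 residual degrees of freedom and has little power. Whether the correlation or the few degrees of freedom ended the calls was not tested. Members called are counted over all genes tested and, in those words, adjusted over the list alone.

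The genes named in the text followed a rule written before the data were examined: a fixed set of senescence, p53 and ribosome genes with SNORA13 and its host transcript; the 10 largest changes in each direction among called genes whose groups did not overlap, at a CPM of 5 or more in the higher group; and up to 4 members per list with the smallest p in that contrast. Some genes that the rule names are not reported here. Histone and ribosomal protein genes have near-identical copies or pseudogenes, so their reads can be split between copies, and the values of single members are uncertain. Overlapping and antisense genes are uncertain too, since the strand setting of the counting is not given in the sources used here.

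The same clone was sampled without and with 4-OHT, so clone numbers pair libraries by design. Over the 16544 genes, the difference between clones without 4-OHT correlated with that with 4-OHT at r = 0.309 for WT and 0.005 for KO. The fit with clone as a block was an alternative, given beside each result whose call it changed. It cannot estimate KO minus WT. The other alternatives fixed before the data were examined were median-ratio factors (RLE), library size only, no filter beyond 1 read, limma-voom on the recovered reads, a fit of only the 4 libraries compared, leaving out the 4 genes that held over 1% of the reads of a library, fry and estimated correlations for lists, and each library left out in turn. Pseudocounts of 0.01 and 1, a filter at a mean RPKM of 1, and camera tests of lists with each library left out were added after the data had been seen.

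The pipeline was tested on simulated data for the same 16544 genes, with a dispersion of 0.02 and 200 changed genes of 3 sizes. At 2-fold it called 62.7% of changed genes for the WT response, 70.1% for the KO response, 67.2% and 65.7% for KO minus WT without and with 4-OHT, and 17.9% for the interaction. At 4-fold it called 100%, 100%, 98.5%, 98.5% and 93.9%, and at 1.5-fold 7.5%, 1.5%, 7.5%, 1.5% and 0%. Between 7.3% and 12.9% of its calls were unchanged genes, more than the share of 0.05 that the threshold aims at. The data had 1054 to 9208 called genes per comparison. Simulating only 200 changed genes makes the adjusted threshold stricter, so the shares called do not carry over to the data. Changed genes were also drawn only among genes with more reads than the filter asks for, so these shares leave out low genes. Every gene had the same dispersion, and no lasting difference between clones was simulated, so the share of false calls does not carry over either. With camera, a simulated list of 40 genes shifted by 0.5 on the log2 scale was called, and 2 of 100 random lists fell under 0.05. Simulated genes were drawn independently of each other, so this did not test the preset correlation for lists whose members vary together. Tables were read with Python 3.11.15, pandas 2.3.3 and numpy 2.4.6, and drawn with matplotlib 3.10.9. Robust moderation used statmod 1.5.0.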

Results

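The transcriptome of BJ-HRAS fibroblasts was measured in 8 libraries, from 2 WT and 2 SNORA13 KO clones, each without and with 4-OHT for 7 days. BJ is a skin fibroblast line. In cells of this kind 4-OHT, an oestrogen receptor ligand, is used to switch on a receptor-HRAS fusion, and sustained RAS activity is a known route to senescence, a lasting arrest of division. SNORA13 is an H/ACA small nucleolar RNA, a class that guides pseudouridylation of other RNAs, and the series concerns the part of a snoRNA in ribosome biogenesis and senescence. Library totals were 22.1 to 24.9 M reads. Clones of a group correlated at r = 0.9836 to 0.9921 over genes on the log2 scale. The first principal component (74.0% of the variance) separated libraries without and with 4-OHT, and the second (9.4%) had positive scores in all 4 WT libraries and negative scores in all 4 KO libraries. The RNA of the signal recognition particle (RN7SL1 and RN7SL2) took 9.18% to 10.13% of the reads of the 4 libraries without 4-OHT. With 4-OHT it took 9.72% in WT clone 15, 15.37% in WT clone 54, and 16.1% and 14.77% in KO clones 66 and 69.

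SNORA13 (ENSG00000238363.1) was read first, since it checks the genotype labels, though not the reading of the minus sign as 4-OHT negative. It lies on chromosome 5 at 112161485 to 112161617 (GRCh38, plus strand), inside its host EPB41L4A-AS1 (ENSG00000224032.6, a long noncoding RNA at 112160526 to 112164276, plus strand), which in turn lies within the span of the minus-strand gene EPB41L4A (112142441 to 112419316). The WT libraries held 6 and 4 SNORA13 reads without 4-OHT and 5 and 7 with it (clones 15 and 54), 1.36 to 2.25 RPKM. All 4 KO libraries held 0 reads, and a count of 0 allows up to 3 reads, or 0.93 to 0.98 RPKM, in each. These limits cover counting error only. EPB41L4A-AS1 was read in every library. It measured 4.17 ± 0.16 RPKM in WT and 7.21 ± 0.60 in KO without 4-OHT (SD, n = 2 clones), a log2 difference of 0.77 ± 0.12 (SE; limma adjusted p = 0.0183). This call ended without WT clone 54 (adjusted p = 0.0671), KO clone 66 (0.0906) or KO clone 69 (0.151). With 4-OHT it fell to 1.91 ± 0.06 in WT and 2.23 ± 0.21 in KO, with no call between the genotypes (log2 difference 0.21 ± 0.12, adjusted p = 0.297).

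**Figure D1:**
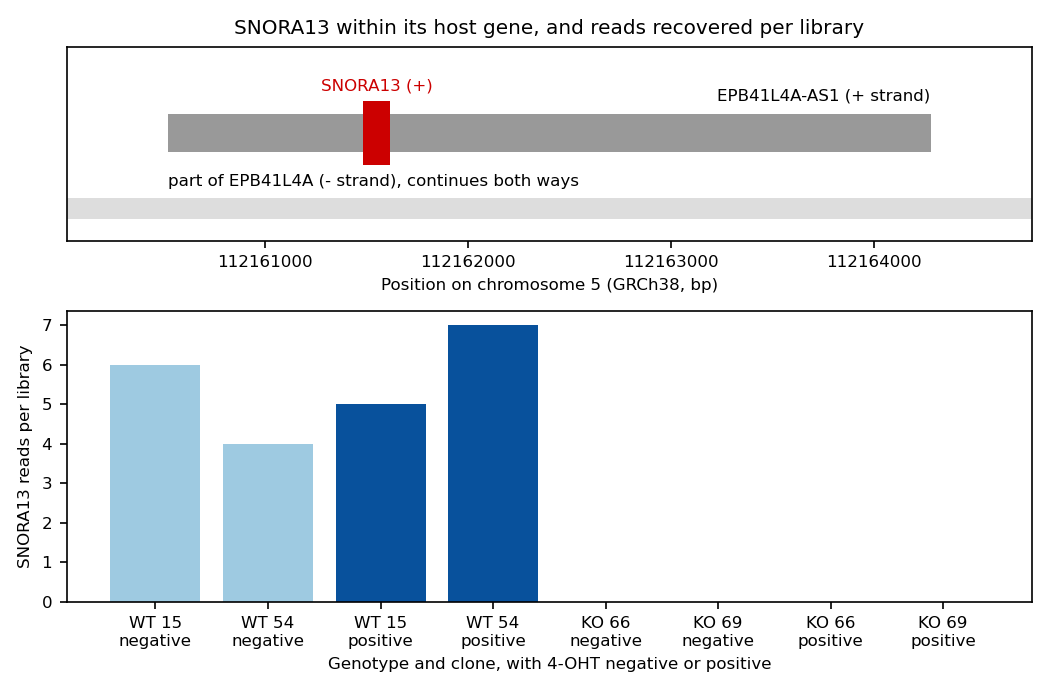
Upper panel, SNORA13 (red) in its host EPB41L4A-AS1 and a part of EPB41L4A along chromosome 5 (GRCh38, bp). Lower panel, SNORA13 reads in each of the 8 libraries (bars, not scaled), named by genotype, clone and 4-OHT; the 4 WT libraries hold 4 to 7 reads and the 4 KO libraries 0.

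The first comparison asked how WT clones responded to 4-OHT. Genes that RAS-MAPK signalling is known to induce rose together: 19 of the 23 tested members rose and 2 fell (median 4.28-fold; camera adjusted p = 1.32e-07; adjusted p = 0.131 with an estimated correlation; 19 rose and 3 fell adjusted over the list alone). SPRY4, a feedback inhibitor of the pathway, rose from 4.72 ± 0.58 to 65.1 ± 2.5 RPKM, 13.6-fold, SPRY2 rose 9.71-fold, PHLDA1 8.5-fold and SPRED1 4.94-fold. HRAS, whose reads can come from a transgene as well as the endogenous gene, measured 246 ± 16 RPKM without and 292 ± 19 with 4-OHT (log2 0.25 ± 0.08, adjusted p = 0.0423). Its call ended without the untreated (adjusted p = 0.136) or the treated library of clone 54 (0.207), with the clone block (0.0634), library size only (0.102), no filter (0.0715), only the 4 libraries compared (0.117) and abundant genes left out (0.0506).

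Targets of p53 rose in the WT clones, 34 of 47 members against 4 that fell (median 1.79-fold; camera adjusted p = 1.43e-06; adjusted p = 0.347 with an estimated correlation; 35 and 5 adjusted over the list alone). CDKN1A, which encodes the cyclin-dependent kinase inhibitor p21, rose from 146 ± 21 to 702 ± 17 RPKM, 4.82-fold (adjusted p = 3.76e-05). MDM2, the ubiquitin ligase of p53, rose 2.61-fold, the decoy death receptor TNFRSF10D 8.65-fold and the nuclease AEN 3.8-fold. CDKN2B, which encodes p15, rose 4.23-fold. CDKN2A had 0 reads in all 8 libraries and IL6 had 0 to 9 reads per library. Of the 34 SASP members tested, 19 rose and 9 fell (camera adjusted p = 0.0145; adjusted p = 0.216 with an estimated correlation; 20 and 10 adjusted over the list alone). The cytokine IL1B rose from 2.72 ± 0.68 to 93.4 ± 8.1 RPKM and the chemokine CXCL8 from 0.342 ± 0.158 to 82.0 ± 11.1 (adjusted p = 1.6e-05 and 4.8e-05). The collagenase MMP1 rose 45.2-fold, the plasminogen activator PLAT 38.8-fold, stanniocalcin STC1 85.8-fold and the growth factor AREG from 0.4 ± 0.037 to 32.9 ± 9.4 RPKM. IGFBP5 fell 64.9-fold and the adhesion molecule ICAM1 4.7-fold.

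LMNB1 and HMGB2, whose loss is a known mark of senescent cells, fell in WT with 4-OHT. LMNB1 (lamin B1) went from 14.5 ± 2.9 to 7.40 ± 2.08 RPKM and HMGB2 from 50.5 ± 10.5 to 18.3 ± 3.0 (1.97-fold and 2.74-fold, adjusted p = 0.00555 and 0.000484). The cell cycle lists were not called. Of the DNA replication genes 9 of 49 rose and 3 fell, of the mitotic genes 11 of 51 rose and 3 fell, and of the replication-dependent histones 6 of 51 rose and 1 fell (camera adjusted p = 0.402, 0.0744 and 0.0714; adjusted p = 0.906, 0.869 and 0.869 with an estimated correlation). Adjusted over the list alone, 6 and 3, 7 and 2, and 0 and 0 members rose and fell. List medians changed sign without the untreated library of clone 15 (replication −0.094 and mitotic −0.001, log2) or the treated one of clone 54 (replication −0.029 and histones −0.038). With the clone block the mitotic and histone lists were called upward (camera adjusted p = 0.0154 and 0.007). Of the mitotic genes, 40 of 51 had a positive estimate. Among the 3 called lower were the kinesin KIF20A (2.03-fold) and the spindle gene ASPM (1.77-fold), against 11 called higher. The proliferation marker MKI67 measured 5.96 ± 1.34 and 6.02 ± 0.31 RPKM (log2 0.03 ± 0.15, adjusted p = 0.88), and its log2 difference was −0.20 without the untreated library of clone 15 and −0.02 without the treated library of clone 54.

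Ribosome biogenesis factors rose in 72 of 80 cases and fell in 2 (median 1.59-fold; camera adjusted p = 8.51e-17; adjusted p = 0.216 with an estimated correlation; 75 and 2 adjusted over the list alone). The nucleolar factor LYAR rose from 8.95 ± 1.29 to 46.0 ± 2.3 RPKM, the pre-ribosome factors BYSL and WDR12 rose 2.95-fold and 2.46-fold, and nucleolin (NCL) 1.45-fold. DKC1, the pseudouridine synthase of H/ACA particles, rose 2.03-fold. UBTF, a transcription factor of RNA polymerase I, fell 1.46-fold. Large-subunit ribosomal proteins rose in 17 of 47 cases with none called lower (camera adjusted p = 0.0035; adjusted p = 0.617 with an estimated correlation; 14 adjusted over the list alone). The H/ACA and C/D snoRNAs, of which 44 and 42 passed the filter, were not called as lists (camera adjusted p = 0.747 and 0.191).

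Genes of the fibroblast state fell in WT with 4-OHT. Of 40 extracellular matrix genes 26 fell and 6 rose, and of 17 contractile genes 13 fell and none was called higher (camera adjusted p = 1.32e-05 and 1.61e-05; adjusted p = 0.37 and 0.131 with an estimated correlation; 26 and 13 fell adjusted over the list alone). Decorin (DCN) fell from 61.4 ± 10.2 to 0.933 ± 0.051 RPKM, collagen COL3A1 5.41-fold, PCOLCE 5.46-fold and THBS2 3.92-fold. The actin-binding gene LMOD1 fell from 17.1 ± 3.2 to 0.969 ± 0.230 RPKM and CALD1 3.42-fold. Fibroblast markers, a list that shares decorin and other matrix genes with the former, fell in 8 of 13 cases and rose in 3 (camera adjusted p = 0.00192; adjusted p = 0.37 with an estimated correlation; 8 and 3 adjusted over the list alone). The 6 epithelial markers tested were not called as a list (camera adjusted p = 0.43). Among the genes of largest change, the vitamin A enzymes ALDH1A1 (1081 ± 522 to 8.19 ± 0.56 RPKM) and DHRS3 (65.0 ± 47.0 to 0.0982 ± 0.0367), the retinoic acid binder CRABP2 (665 ± 50 to 10.7 ± 0.9) and the muscarinic receptor CHRM2 (55.6 ± 7.8 to 0.494 ± 0.024) fell, and RARRES2 went from 8.85 ± 0.05 RPKM to 1 and 0 reads. The call of DHRS3 ended with limma-voom (adjusted p = 0.0635). TMEM158, known as a RAS-induced gene, rose 89.8-fold and the hyaluronan synthase HAS2 rose from 0.02 ± 0.014 to 11.5 ± 4.4 RPKM.

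Over all genes, limma called 8083 of 16544 between WT with and without 4-OHT, 4176 higher and 3907 lower with 4-OHT, of which 3036 changed at least 2-fold. The share of signal recognition particle RNA rose with 4-OHT in clone 54 and little in clone 15, as given above.

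The second comparison asked the same of the KO clones. Genes of cell division rose together. All 51 mitotic genes and all 51 replication-dependent histones tested rose, as did 46 of 49 DNA replication genes, with none of the 3 lists holding a member called lower (median 5.63-fold, 5.33-fold and 3.56-fold; camera adjusted p = 9.74e-20, 3.5e-19 and 4.09e-15). These lists had adjusted p = 0.297 each with an estimated correlation, and the counts were 51, 51 and 46 adjusted over the list alone. MKI67 rose from 2.18 ± 0.19 to 13.9 ± 0.1 RPKM, 6.16-fold (adjusted p = 1.65e-05). The checkpoint gene MAD2L1 rose 7.26-fold, CKS2 6.41-fold, CDCA3 from 1.26 ± 0.12 to 7.86 ± 0.72 RPKM, the origin recognition gene ORC6 from 1.27 ± 0.20 to 14.8 ± 1.1, the chromatin assembly gene CHAF1A 4.33-fold and the replication clamp PCNA 3.5-fold. HIST1H2AJ rose from 61.7 ± 4.5 to 517 ± 26 RPKM and HIST1H2BO 7.92-fold. LMNB1 rose 3.07-fold (6.48 ± 0.44 to 20.1 ± 0.9 RPKM) and HMGB2 2-fold (20.7 ± 1.6 to 41.8 ± 5.8).

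RAS-MAPK output genes rose in 18 of 23 cases and fell in 3 in the KO clones (median 4.41-fold; camera adjusted p = 6.22e-07; adjusted p = 0.175 with an estimated correlation; 19 and 3 adjusted over the list alone). SPRY4 rose 17.1-fold, PHLDA1 10.3-fold, SPRY2 8.67-fold and HRAS 1.74-fold. Targets of p53 rose in 27 of 47 cases and fell in 6 (median 1.51-fold; camera adjusted p = 0.00112; adjusted p = 0.297 with an estimated correlation; 27 and 6 adjusted over the list alone). CDKN1A rose 3.73-fold, from 77.4 ± 6.3 to 292 ± 57 RPKM, TNFRSF10D 6.52-fold and AEN 4.6-fold. MDM2 rose 1.51-fold (adjusted p = 0.00973), a call that ended without the untreated (0.068) or the treated library of clone 66 (0.0585). Among SASP genes 19 of 34 rose and 12 fell, and the list was not called (camera adjusted p = 0.0641; adjusted p = 0.291 with an estimated correlation; 19 and 12 adjusted over the list alone). It became called with library size only (camera adjusted p = 0.0271, upward) and with fry (adjusted p = 1.65e-05). IL1B rose 14.4-fold, CXCL8 from 0.247 ± 0.279 to 16.2 ± 0.8 RPKM, PLAT 25.1-fold, the urokinase gene PLAU 79.2-fold and STC1 138-fold.

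Ribosome biogenesis factors rose in 71 of 80 cases and fell in 1 (median 1.68-fold; camera adjusted p = 2.86e-15; adjusted p = 0.215 with an estimated correlation; 71 and 1 adjusted over the list alone). LYAR rose 5.84-fold, MRTO4 3.38-fold, DKC1 2.67-fold and NCL 2.03-fold. C/D snoRNAs rose in 17 of 42 cases and fell in 1 (camera adjusted p = 0.0361; adjusted p = 0.233 with an estimated correlation; 15 and 0 adjusted over the list alone), with camera adjusted p = 0.062 without the treated library of clone 66. SNORD96A rose 3.25-fold. Among the H/ACA snoRNAs, a list that was not called (camera adjusted p = 0.222), SNORA21 rose 7.05-fold, from 6.98 ± 0.99 RPKM. Contractile genes fell in 14 of 17 cases, matrix genes in 25 of 40 with 7 rising, and fibroblast markers in 9 of 13 with 4 rising (camera adjusted p = 6.22e-07, 8.96e-05 and 0.0119; adjusted p = 0.116, 0.297 and 0.297 with an estimated correlation). Adjusted over the list alone, 15, 25 and 9 fell. The 6 epithelial markers tested, of which 4 fell and 1 rose, were not called as a list (camera adjusted p = 0.157). Transgelin (TAGLN) fell 4.63-fold, CCN2 3.86-fold, decorin (DCN) from 73.4 ± 7.9 to 1.08 ± 0.05 RPKM and the fibroblast protease FAP 18-fold. As in WT, DHRS3 and ALDH1A1 fell (to 0.0501 ± 0.0164 and 10.5 ± 0.2 RPKM; DHRS3 lost its call with limma-voom, adjusted p = 0.066), and TMEM158 and HAS2 rose (to 417 ± 29 and 27.0 ± 3.4 RPKM).

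In the KO clones limma called 9208 of 16544 genes, 4752 higher and 4456 lower with 4-OHT, of which 3948 changed at least 2-fold. The share of signal recognition particle RNA rose with 4-OHT in both KO clones. Over the 16544 genes, the KO and WT responses correlated at Pearson r = 0.835 and Spearman rho = 0.788. Genes are not independent replicates, and these responses share no library. Both genotypes called 3231 genes higher and 3006 lower, where independent lists of these sizes would share 1199.5 and 1052.3, and 97 genes were called in opposite directions.

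The third comparison set KO against WT clones without 4-OHT. Cell division genes were lower in KO: 45 of 51 mitotic genes, 29 of 49 DNA replication genes and 18 of 51 replication-dependent histones, with none called higher (median 2.53-fold, 1.79-fold and 1.64-fold lower; camera adjusted p = 2.84e-36, 2.95e-21 and 7.22e-17). Their adjusted p was 0.315, 0.321 and 0.321 with an estimated correlation, and the counts were 50, 41 and 39 adjusted over the list alone. Without WT clone 15, WT clone 54, KO clone 66 or KO clone 69 in that order, the counts were 49, 35, 3 and 0 for mitotic, 34, 10, 0 and 0 for replication and 24, 2, 0 and 0 for histone genes. The lists stayed lower, with log2 medians of −1.58 to −1.11, −1.01 to −0.69 and −0.88 to −0.54. MKI67 measured 5.96 ± 1.34 RPKM in WT and 2.18 ± 0.19 in KO, 2.63-fold lower (log2 −1.40 ± 0.15, adjusted p = 0.00838). CDCA3 was 3.47-fold lower, KIF20A 3.17-fold, DLGAP5 3.11-fold, thymidine kinase TK1 2.97-fold, CHAF1A 2.15-fold and PCNA 1.71-fold. HIST1H2AJ was 1.7-fold and HIST1H2BE 2.14-fold lower. LMNB1 and HMGB2 were 2.21-fold and 2.4-fold lower in KO. Targets of p53 were lower in 10 of 47 cases and higher in 1 (median 1.14-fold lower; camera adjusted p = 8.99e-05; adjusted p = 0.321 with an estimated correlation; 14 and 1 adjusted over the list alone), and 11, 5, 1 and 0 were lower without these libraries in the same order. CDKN1A was 1.89-fold lower (146 ± 21 against 77.4 ± 6.3 RPKM, adjusted p = 0.0203), the DNA repair gene DDB2 2.17-fold, the carboxylesterase CES2 1.85-fold and TNFRSF10D 1.56-fold. RAS-MAPK output and SASP genes were not called as lists (camera adjusted p = 0.469 and 0.493). The prostaglandin synthase PTGS2 was 4.12-fold higher and the chemokine CCL26 lower in KO (1.04 ± 0.20 against 0.233 ± 0.004 RPKM).

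Genes of ribosome components leaned higher in KO without 4-OHT. Ribosome biogenesis factors were not called as a list (1 of 80 higher and 1 lower, camera adjusted p = 0.722). Large-subunit and small-subunit ribosomal proteins were called higher as lists through small shifts, of which 1 of 47 and 3 of 32 members passed (median 1.18-fold and 1.21-fold higher; camera adjusted p = 1.01e-09 and 4.4e-08; adjusted p = 0.321 each with an estimated correlation; 8 and 13 adjusted over the list alone). RPL13A and RPS20 were 1.27-fold and 1.35-fold higher. The snoRNA host genes were higher in 4 of 17 cases and C/D snoRNAs in 5 of 42 (camera adjusted p = 8.6e-05 and 0.00821; adjusted p = 0.315 each with an estimated correlation; 5 and 9 adjusted over the list alone). SNHG7 was 1.45-fold, SNHG29 1.69-fold and SNORD104 1.74-fold higher. H/ACA snoRNAs were not called as a list (1 of 44 higher, camera adjusted p = 0.163). The genes around SNORA13 on 5q22 were not called as a list (1 of 16 higher and 1 lower, camera adjusted p = 0.469). The potassium channel gene KCNN2 was 3.52-fold higher and the kinase gene CAMK4 lower in KO (1.05 ± 0.48 against 0.0805 ± 0.0158 RPKM), by a log2 difference that lay between −3.60 and −0.90 over the alternatives. The CAMK4 call ended with limma-voom (adjusted p = 0.144), no filter (0.0887), only the 4 libraries compared (0.0533) and a pseudocount of 1 (0.0798). Among the largest differences, IGFBP2 measured 1.55 ± 1.92 RPKM in WT and 83.1 ± 7.1 in KO, EEF1A2 1.01 ± 0.98 and 24.5 ± 7.2, and FHOD3 1.41 ± 0.12 and 9.94 ± 0.01. ZNF426 (2.25 ± 0.28 and 0.0577 ± 0.0009), ISYNA1 (5.53 ± 0.66 and 0.448 ± 0.053) and NXN (21.4 ± 4.2 and 2.71 ± 1.61) were lower in KO.

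Over all genes, limma called 1054 of 16544 between KO and WT without 4-OHT, 435 higher and 619 lower in KO, of which 384 differed at least 2-fold. The count was 1832 without WT clone 15, 384 without WT clone 54, 19 without KO clone 66 and 5 without KO clone 69. Of the 37 called genes named for this comparison, none turned, and 1 lost its call without WT clone 15 (adjusted p = 0.0673), 12 without WT clone 54 (0.0509 to 0.0942), 30 without KO clone 66 (0.054 to 0.168) and 34 without KO clone 69 (0.0563 to 0.196). In a fit of only the 4 libraries compared 20 lost it (0.0533 to 0.105), and with no filter beyond 1 read 13 did (0.0522 to 0.105), CDKN1A, LMNB1, HMGB2 and EPB41L4A-AS1 among them both times.

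The fourth comparison set KO against WT clones with 4-OHT. Here cell division genes were higher in KO: 50 of 51 replication-dependent histones, 40 of 49 DNA replication genes and 39 of 51 mitotic genes, with none called lower (median 2.6-fold, 1.86-fold and 1.82-fold; camera adjusted p = 8.2e-35, 2.16e-20 and 5.09e-23). Their adjusted p was 0.299, 0.357 and 0.357 with an estimated correlation, and the counts were 51, 44 and 49 adjusted over the list alone. Without WT clone 15, WT clone 54, KO clone 66 or KO clone 69 in that order, the counts were 34, 50, 36 and 10 for histone, 5, 38, 10 and 1 for replication and 5, 34, 9 and 2 for mitotic genes. The lists stayed higher, with log2 medians of 1.08 to 1.66, 0.73 to 1.09 and 0.70 to 1.07. HIST1H2AJ measured 112 ± 13 RPKM in WT and 517 ± 26 in KO, HIST1H2BM was 4.76-fold and HIST1H1A 2.92-fold higher. MKI67 was 2.29-fold higher in KO (6.02 ± 0.31 against 13.9 ± 0.1 RPKM, adjusted p = 0.00718), KIF20A 2.35-fold, ASPM 2.14-fold, CKS2 2.12-fold, the clamp loader genes RFC3 and RFC5 2.21-fold and 1.87-fold, and geminin (GMNN) 2.04-fold. LMNB1 (7.40 ± 2.08 against 20.1 ± 0.9 RPKM) and HMGB2 (18.3 ± 3.0 against 41.8 ± 5.8) were 2.75-fold and 2.29-fold higher.

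Targets of p53 were lower in KO with 4-OHT, 21 of 47 with none called higher (median 1.31-fold lower; camera adjusted p = 1.37e-11; adjusted p = 0.299 with an estimated correlation; 26 adjusted over the list alone), and 3, 16, 13 and 3 were lower without the same 4 libraries in turn. CDKN1A measured 702 ± 17 RPKM in WT and 292 ± 57 in KO, 2.43-fold lower (adjusted p = 0.00553). MDM2 was 1.71-fold lower, TNFRSF10D 2.07-fold, CES2 2.04-fold, the antiproliferative gene BTG2 2.59-fold and the kinase PLK3 1.49-fold. Among SASP genes 8 of 34 were lower and 3 higher (camera adjusted p = 0.0479; adjusted p = 0.299 with an estimated correlation; 9 and 4 adjusted over the list alone). Without these libraries 4, 5, 4 and 3 were lower. The list lost its call without WT clone 15 (0.0726), WT clone 54 (0.0517) or KO clone 66 (0.0738). CXCL8 was 5.02-fold lower in KO (82.0 ± 11.1 against 16.2 ± 0.8 RPKM, adjusted p = 0.0316), MMP3 3.59-fold, PLAT 2.45-fold and IL1B 2.44-fold (93.4 ± 8.1 against 38.3 ± 5.9 RPKM, adjusted p = 0.0228), and AREG was 2.63-fold higher. RAS-MAPK output genes were not called as a list (1 of 23 higher and 4 lower, camera adjusted p = 0.192). HRAS measured 292 ± 19 RPKM in WT and 349 ± 21 in KO (log2 0.26 ± 0.08, adjusted p = 0.0848).

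Contractile genes were lower in 9 of 17 cases with none called higher (camera adjusted p = 6.01e-05; adjusted p = 0.113 with an estimated correlation; 10 adjusted over the list alone), among them TAGLN (2.12-fold), MYL9 (2.17-fold) and TPM1 (1.64-fold). Ribosome biogenesis factors were not called as a list (7 of 80 higher and 2 lower, camera adjusted p = 0.472): fibrillarin (FBL) was 1.46-fold, UBTF 1.3-fold and NCL 1.21-fold higher, and SBDS, which acts in the release of EIF6 from the large subunit, was 1.37-fold lower. C/D and H/ACA snoRNAs leaned higher in KO, with 4 of 42 and 2 of 44 members called (camera adjusted p = 6.01e-05 and 0.000745; adjusted p = 0.113 and 0.357 with an estimated correlation; 4 and 0 adjusted over the list alone). The H/ACA list lost its call without WT clone 15 (0.0666) and with fry (0.0998). The adaptor SQSTM1 was 2.29-fold and the quinolinate enzyme QPRT 5.42-fold lower in KO. The trypsinogen gene PRSS3 measured 0.152 ± 0.067 RPKM in WT and 46.0 ± 7.0 in KO, IGFBP2 0.398 ± 0.471 and 31.9 ± 4.9, AKR1C2 was 4.93-fold higher, EPHB6 measured 0.132 ± 0.010 and 1.64 ± 0.01, and ADGRE1 measured 2.98 ± 0.20 in WT against 0 and 1 reads in the KO libraries. PURPL, a long noncoding RNA known as a p53 target (3.05 ± 0.35 and 0.0931 ± 0.0289 RPKM), ZNF426 (1.83 ± 0.18 and 0.115 ± 0.036), TGFB2 (0.95 ± 0.48 and 0.0911 ± 0.0675) and CAMK4 (1.35 ± 0.91 and 0.215 ± 0.042) were lower in KO, and NXN was 5.73-fold lower. The log2 differences of TGFB2 and CAMK4 lay between −3.49 and −0.82 and between −2.73 and −0.89 over the alternatives.

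Over all genes, limma called 2372 of 16544 between KO and WT with 4-OHT, 1105 higher and 1267 lower in KO, of which 545 differed at least 2-fold. Signal recognition particle RNA took 9.72% of the reads of WT clone 15 with 4-OHT and 14.77% to 16.1% in the other 3 treated libraries. The fold changes of KO over WT without and with 4-OHT correlated at Pearson r = 0.152 and Spearman rho = 0.078 over the 16544 genes, which are not independent replicates. Both conditions called 83 genes higher and 123 lower in KO (206 in all), where independent lists would share 29.1 and 47.4. In opposite directions 229 genes were called, for which no number under independence was computed. The 2 comparisons use different libraries of the same 4 clones, and the other 2 splits of the clones into pairs, which call no genes, correlate at r = 0.222 and 0.171 in this way. The count of 2372 was 364 without WT clone 15, 1359 without WT clone 54, 860 without KO clone 66 and 170 without KO clone 69. Of the 44 called genes named for this comparison, none turned, and 14, 5, 7 and 24 lost their call without these libraries in that order (adjusted p from 0.0504 to 0.173), CXCL8, IL1B, NCL and UBTF among them each time. With no filter beyond 1 read 6 did (0.0532 to 0.108), namely CXCL8, IL1B, MDM2, NCL, TGFB2 and CAMK4, and CXCL8 also with a pseudocount of 0.01 (0.105), NCL with library size only (0.0689) and only the 4 libraries compared (0.0555), TGFB2 with limma-voom (0.0506), and CAMK4 with limma-voom (0.137), only the 4 libraries (0.0564) and a pseudocount of 1 (0.0627).

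**Figure D2:**
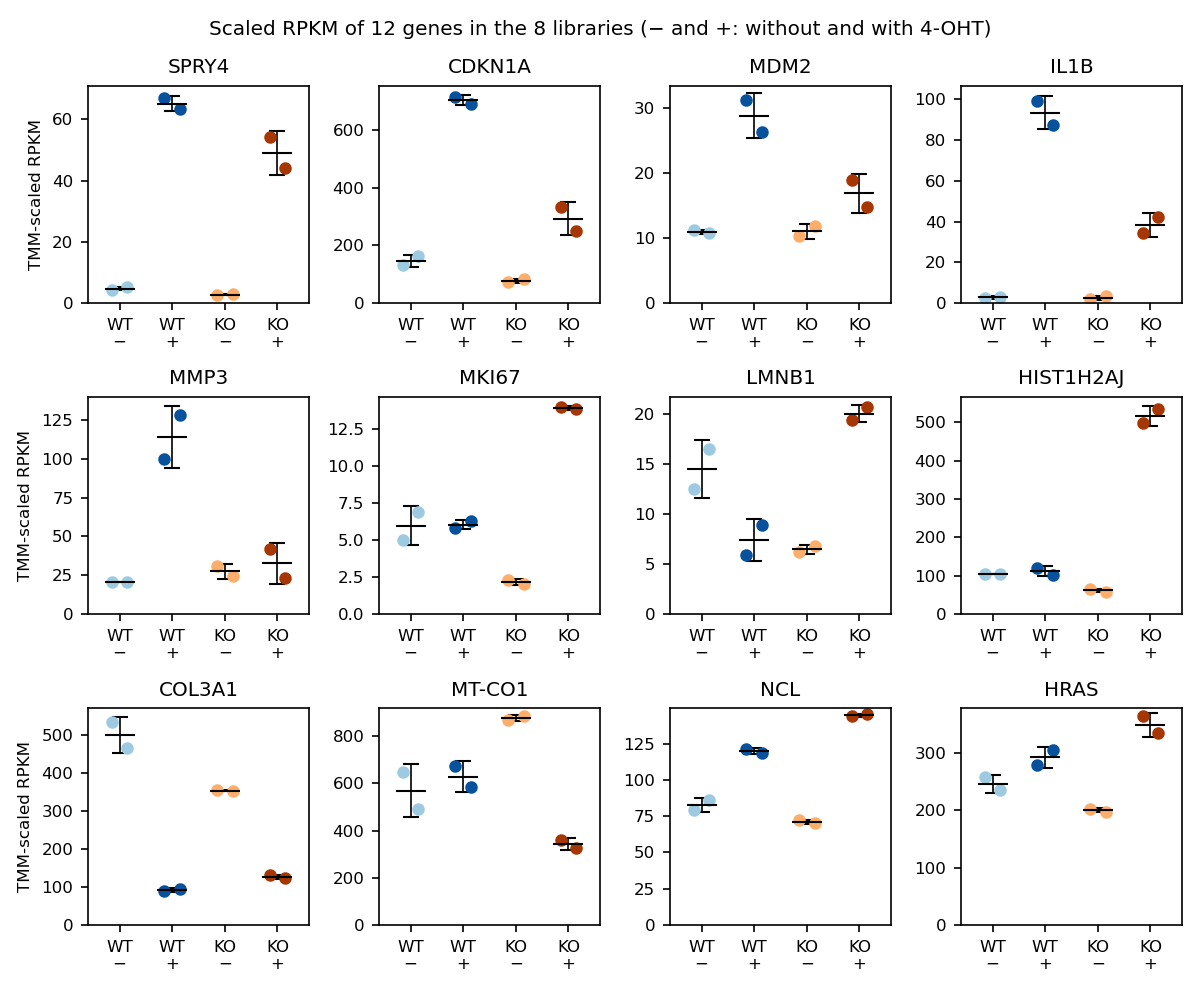
TMM-scaled RPKM (vertical axes, linear from 0) of 12 genes in the 8 libraries, with points for clones, horizontal bars for group means and whiskers for ± 1 SD (n = 2 clones); WT and KO are marked − and + for without and with 4-OHT. SPRY4 rises in both genotypes, CDKN1A stays lower in KO with 4-OHT (292 against 702 RPKM), and MKI67 rises in KO alone (2.18 to 13.9 RPKM).

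The fifth comparison tested whether the 4-OHT response itself differed between KO and WT clones. It did so for the genes of cell division, whose response was higher in KO for all 51 mitotic genes, 50 of 51 replication-dependent histones and 44 of 49 DNA replication genes, with none called the other way (median 4.79-fold, 4.59-fold and 3.32-fold; camera adjusted p = 6.53e-44, 6.23e-42 and 1.68e-32). Their adjusted p was 0.247, 0.247 and 0.274 with an estimated correlation, and the counts were 51, 51 and 46 adjusted over the list alone. With each of the 8 libraries left out the counts were 36 to 51, 28 to 51 and 21 to 46, lowest without the treated (36 and 28) or untreated library (21) of KO clone 69. The log2 response of MKI67 was 0.03 in WT and 2.62 in KO, a difference of 2.59 ± 0.22 (SE, adjusted p = 0.00526). KIF20A differed by 2.90, CDCA3 by 2.71 (2.11 with a pseudocount of 1), the ribonucleotide reductase gene RRM2 by 2.51, CHAF1A by 1.73 and PCNA by 1.52. HIST1H2AJ differed by 2.98 and HIST1H2BE by 2.23. LMNB1 and HMGB2 fell in WT and rose in KO, and differed by 2.60 ± 0.28 and 2.46 ± 0.25.

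The response of p53 targets was called lower in KO as a list, with 3 of 47 members lower and 1 higher (camera adjusted p = 0.0112; adjusted p = 0.603 with an estimated correlation; 5 and 1 adjusted over the list alone), and the list lost its call without the treated library of KO clone 69 (0.0574) and with fry (0.134). The members called lower were 0 to 6 with each library left out. The ribonucleotide reductase subunit RRM2B (−0.78 ± 0.18, adjusted p = 0.0438, or 0.0729 with the clone block) and the fucosidase FUCA1 (−0.71) rose less or fell more in KO, and DDB2 (1.02) rose more. The responses of CDKN1A (−0.37 ± 0.21, adjusted p = 0.328), MDM2 (−0.79 ± 0.20, 0.0634), IL1B (−1.23 ± 0.38, 0.0981) and CXCL8 (−1.75 ± 0.76, 0.206, with log2 differences of −2.68 to −0.82 over its alternatives) did not pass the threshold. CXCL8 passed it without the untreated library of KO clone 66 (0.037) and with a pseudocount of 1 (0.00624), in a range of 0.00624 to 0.526 over its alternatives, and MDM2 with limma-voom (0.0252, in a range of 0.0252 to 0.204). RAS-MAPK output genes were not called as a list (1 of 23 higher and 1 lower, median log2 difference 0.06 with a camera direction of lower, adjusted p = 0.932), nor were SASP genes (1 of 34 higher and 2 lower, camera adjusted p = 0.295). Among their members the phosphatase DUSP6 (−0.88) rose less in KO, the matrix protease MMP3 (−2.26) rose in WT from 20.6 ± 0.2 to 114 ± 20 RPKM and measured 27.6 ± 4.8 and 32.8 ± 13.3 in KO, NRG1 differed by −1.28 and EGR1 by 1.25. HRAS differed by 0.55 ± 0.12 (adjusted p = 0.0358, or 0.0565 with the clone block).

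Ribosome biogenesis factors were not called as a list (4 of 80 higher and 2 lower, camera adjusted p = 0.265). NCL differed by 0.48 ± 0.10 (adjusted p = 0.0298, or 0.0504 with the clone block) and UBTF by 0.62, and SBDS by −0.61. The contractile list was lower in response, with 6 of 17 members lower (camera adjusted p = 9.18e-05; adjusted p = 0.247 with an estimated correlation; 8 adjusted over the list alone), among them CCN2 (−1.07) and TAGLN (−1.03). Fibroblast markers were called higher in response as a list, with 4 of 13 members higher (camera adjusted p = 0.0321, or 0.117 with the clone block and 0.147 with fry; adjusted p = 0.575 with an estimated correlation; 4 adjusted over the list alone). That call also ended without the untreated library of WT clone 15 (0.211), of KO clone 69 (0.0543), or the treated library of WT clone 54 (0.0514) or KO clone 66 (0.0559). The collagen COL3A1 fell less in KO (0.96) and the lysyl hydroxylase PLOD2 fell in KO (−1.07). PRSS3 (3.96) rose in KO from 2.27 ± 0.16 to 46.0 ± 7.0 RPKM with 1 to 5 reads in each WT library, and the keratin KRT34 (−3.40, or −2.61 with a pseudocount of 1), netrin NTN4 (−2.77) and FHOD3 (−2.67) had lower responses in KO.

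Over all genes, limma called a different response in 1231 of 16544, 717 higher and 514 lower in KO. By the sign of the estimates alone, 169 had responses of the same sign that were smaller in KO, 626 of the same sign that were larger in KO, and 436 of opposite signs, of which 95 were called in both genotypes. The count of 1231 was 2088, 889, 474 and 888 without the untreated libraries of WT clones 15 and 54 and the treated ones of 15 and 54, and 362, 287, 589 and 283 without the untreated libraries of KO clones 66 and 69 and the treated ones of 66 and 69. Of the 34 called genes named for this comparison, none turned, and in the same order 1, 1, 10, 4, 12, 14, 6 and 11 lost their call (adjusted p from 0.0507 to 0.152), HRAS, NCL, UBTF and RRM2B among them. With no filter beyond 1 read 10 did (0.0587 to 0.127), namely HRAS, NCL, RRM2B, FUCA1, MMP3, NRG1, DUSP6, EGR1, TAGLN and CCN2, and PRSS3 did with a pseudocount of 0.01 (0.0559).

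**Figure D3:**
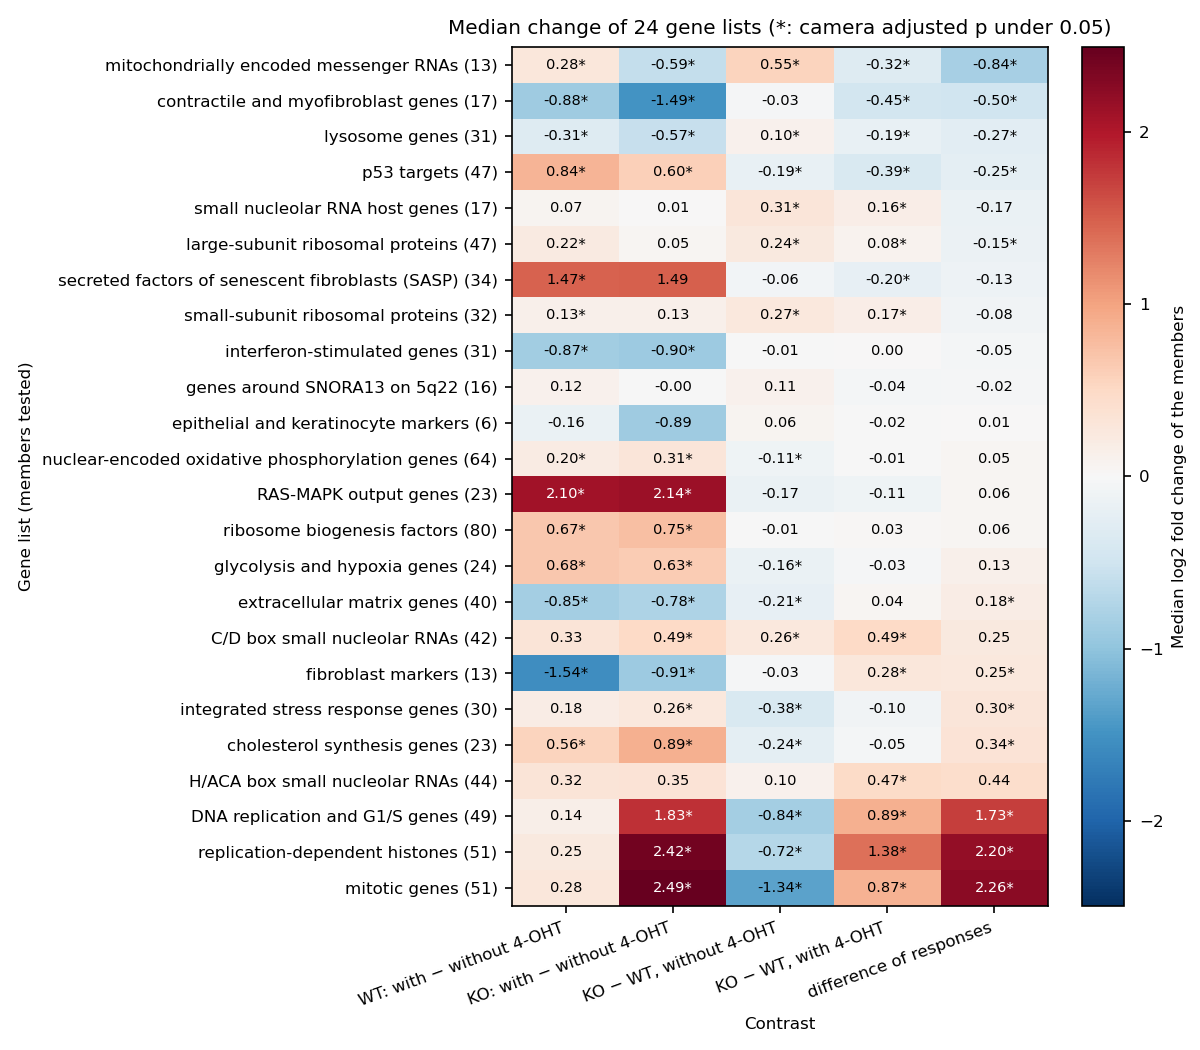
Median log2 fold change of the members (colour and number) of 24 gene lists (vertical axis, with the number of members tested) in the 5 contrasts (horizontal axis); an asterisk marks a camera adjusted p under 0.05 at the preset correlation. Mitotic genes have medians of 0.28 in WT and 2.49 in KO for the 4-OHT response, and RAS-MAPK output genes 2.10 and 2.14.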

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

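The tests of scaling, of the difference without 4-OHT alone, of RAS output, of whole chromosomes and of a deletion around SNORA13 were chosen after their results had been seen. The results here are those whose 4-OHT response differed between KO and WT clones by the interaction test.

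Genes of cell division rose more after 4-OHT in the KO clones: the interaction had camera adjusted p = 6.53e-44 for mitotic genes, 6.23e-42 for replication-dependent histones and 1.68e-32 for DNA replication genes (adjusted p = 0.247, 0.247 and 0.274 with an estimated correlation). The log2 responses differed by 2.59 for MKI67, 2.90 for KIF20A, 2.71 for CDCA3, 2.60 for LMNB1, 2.46 for HMGB2, 2.51 for RRM2, 1.73 for CHAF1A, 1.52 for PCNA, 2.98 for HIST1H2AJ and 2.23 for HIST1H2BE. Over 3 scalings the lowest list median was 1.717. The TMM factors lay between 0.9398 and 1.035, so a change of scaling could move it little, and this did not test scaling. Against a single library stands the lowest list median of 1.61 over the 8 libraries left out. List medians of KO minus WT (log2) without and with 4-OHT were −1.34 and 0.87 for mitotic genes. They were −0.84 and 0.89 for replication genes and −0.72 and 1.38 for histones. The lower level without 4-OHT in KO was thus the larger part of the difference for mitotic genes and the smaller part for histones. It is not the whole difference, since 39 of 51 mitotic genes were higher in KO than in WT with 4-OHT. That count was 5, 34, 9 and 2 without WT clones 15 and 54 and KO clones 66 and 69, while the list median stayed between 0.70 and 1.07 (log2). RAS output in KO was 102.1% of that in WT (median response on the log2 scale), so the median member response was no weaker. Members went both ways (DUSP6 −0.88 and EGR1 1.25), and with 4-OHT 4 of 23 were called lower in KO and 1 higher. With 2 clones per genotype, a weaker RAS signal in KO is not excluded. The loss of SNORA13 and other differences between the clones both stay open, and neither was tested against the other.

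The 1231 genes of the interaction stand beside 0 in each of the other splits of the 4 clones into pairs, as do the 1054 and 2372 genes between KO and WT without and with 4-OHT. In each of these 3 results 1 of the 3 splits, the real one, gave as many genes, and 3 splits cannot give a share under 0.05. The other splits pair a WT with a KO clone, so a KO minus WT difference of any cause adds to their spread and removes calls. Their lack of calls is therefore no independent reference.

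Between KO and WT clones, 206 genes differed in the same direction without and with 4-OHT, 123 lower and 83 higher in KO. In opposite directions 229 genes were called. The same 4 clones supply both comparisons, whose fold changes correlated at Pearson r = 0.152, against 0.222 and 0.171 in the other 2 splits of the clones, which called no genes. Against a gain or loss of whole chromosomes, the largest chromosome median was 0.085 (log2, either way). For segments of 50 neighbouring tested genes, the largest median of 1 sign, the smaller of those without and with 4-OHT, was 0.245, on chromosome 19. A deletion that takes in most genes around SNORA13 would lower the 5q22 list, whose lower median over 16 tested genes was −0.04. Loss of a few neighbours would not move this median. EPB41L4A, which spans SNORA13, had 0 to 7 reads per library, too few to test. Without 4-OHT 1 member was called lower in KO (CAMK4) and 1 higher (KCNN2). With 4-OHT 1 was called lower (CAMK4) and 0 higher, and several alternatives ended the CAMK4 calls. Changes over fewer genes, other mutations and lasting differences in gene regulation between clones stay open, as does SNORA13 itself.

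Further lists differed in response, with camera adjusted p = 0.0112 for p53 targets, 0.0248 for large-subunit ribosomal proteins, 0.0489 for extracellular matrix genes, 9.18e-05 for contractile genes, 0.00111 for cholesterol synthesis, 0.0293 for the integrated stress response, 1.16e-09 for mitochondrially encoded messages, 8.95e-06 for lysosome genes and 0.0321 for fibroblast markers. In the same order, adjusted p = 0.603, 0.72, 0.669, 0.247, 0.3, 0.72, 0.247, 0.247 and 0.575 with an estimated correlation. Leaving out single libraries ended the calls of p53 targets (adjusted p = 0.0574), large-subunit proteins (0.0544 to 0.268), matrix genes (0.122 to 0.302), the integrated stress response (0.063 to 0.346) and fibroblast markers (0.0514 to 0.211). Among single genes, log2 responses in KO minus those in WT were 0.55 for HRAS, 1.02 for DDB2, −0.78 for RRM2B, −0.71 for FUCA1, −2.26 for MMP3, −1.28 for NRG1, −0.88 for DUSP6 and 1.25 for EGR1. They were 0.48 for NCL, 0.62 for UBTF, −0.61 for SBDS, −1.03 for TAGLN, −1.07 for CCN2, −1 for MT-ND6, −1.51 for MT-CO1, −1.02 for SQSTM1, −1.38 for STC2 and 0.84 for ACAT2. They were 3.96 for PRSS3 (3.65 with a pseudocount of 0.01, where its call ended at adjusted p = 0.0559), −3.40 for KRT34, −2.77 for NTN4, −2.67 for FHOD3, 0.96 for COL3A1 and −1.07 for PLOD2.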

How the results depend on the processing

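Pseudocounts of 0.01 and 1, a filter at a mean RPKM of 1, and camera tests of lists with each library left out were added after the data had been seen. The counts of genes for the 4-OHT responses stayed within 1.5 times of 8083 in WT and 9208 in KO under each alternative run (8272 and 9296 with the clone as a replicate block). Without 4-OHT, the 1054 genes between KO and WT became 246 with no filter beyond 1 read (36398 genes tested), 1763 with limma-voom, 117 in a fit of only the 4 libraries compared, and 5 to 1832 with each library left out. With 4-OHT, 2372 became 996 with no filter and 170 to 1359 with each library left out. The 1231 genes of the interaction became 438 with no filter, 1339 with the block, 1768 with limma-voom, and 283 to 2088 with each library left out. A library left out leaves 1 clone in its group, which is then assumed to vary like the others. More genes were tested with no filter, and the smaller fits had fewer libraries, but what caused these changes in the counts was not tested.

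With library size only, the median of all genes moved by less than 0.1 (log2), and the share of calls that were higher was 44.6% in place of 51.7% for the WT response and 65.2% in place of 58.2% for the interaction. MKI67 in WT, at 0.03 and not called, turned to −0.048 with library size only and lay between −0.195 and 0.259 with each library left out. Of 24 lists, 15, 17, 15, 14 and 12 were called in the 5 comparisons, and 0 in each with an estimated correlation. For KO against WT with 4-OHT, 9 to 15 were called with each library left out. With fry, which tests whether members move 1 way on average rather than whether they differ from other genes, 16, 18, 10, 9 and 8 were called. It ended the calls of small-subunit and mitochondrially encoded genes in WT (0.0696 each) and of the integrated stress response in KO (0.0734). Without 4-OHT it ended those of histones (0.0711), matrix (0.185), integrated stress response (0.155), oxidative phosphorylation (0.241) and lysosome genes (0.0875). With 4-OHT it ended those of large-subunit (0.284), small-subunit (0.0998), snoRNA host (0.0741), H/ACA (0.0998), mitochondrially encoded (0.109) and fibroblast genes (0.0741), and in the interaction those of p53 targets (0.134), large-subunit (0.355), matrix (0.279), integrated stress response (0.464) and fibroblast genes (0.147). Fry also called lists that camera had not. In WT these were C/D snoRNAs (0.0159, with 10 members called higher and 3 lower), 5q22 genes (0.0479, with 5 and 3) and epithelial markers (0.000185, with 1 and 2). In KO they were SASP genes (1.65e-05, with 19 and 12) and epithelial markers (4.92e-05, with 1 and 4). Between genotypes with 4-OHT it called epithelial markers (0.0479, with 1 and 1), and in the interaction SASP genes (0.0488, with 1 and 2). Members of these lists thus went both ways. With the block, calls changed for HRAS in WT (0.0634) and, in the interaction, for HRAS (0.0565), RRM2B (0.0729), NCL (0.0504) and fibroblast markers (0.117), and mitotic genes (0.0154) and histones (0.007) became called in WT; it changed no other call among the named genes and lists. With limma-voom the call of SNORD104 between KO and WT without 4-OHT also ended (0.168), and the other calls of named genes that ended are given with their comparisons. DESeq2's test was not run, since the deposited values are not counts. Of the gene fits, limma-voom alone used the recovered reads, on which a count test could also have been run. At 22.1 to 24.9 M reads SNORA13 gave at most 7 reads in a library, so its level could not be compared between conditions.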

Other observations

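Genes of metabolism and of the interferon response moved with 4-OHT in both genotypes. Of 23 cholesterol synthesis genes 17 rose and 2 fell in WT, and 18 rose and 1 fell in KO (camera adjusted p = 1.61e-05 and 1.86e-06; adjusted p = 0.216 and 0.215 with an estimated correlation; 19 and 2, and 18 and 2, adjusted over the list alone). MVD rose 2.15-fold and NSDHL 2.83-fold in WT, and ACAT2 2.93-fold and MVK 2.58-fold in KO. Without 4-OHT the list was lower in KO, 4 of 23 members with none higher (3.63e-07; 0.315 with an estimated correlation; 11 adjusted over the list alone), with MVD 1.76-fold and ACAT2 1.68-fold lower. Its response was higher in KO, 3 of 23 (0.00111; 0.3; 9 adjusted over the list alone), and with 4-OHT it was not called (0.542). Interferon-stimulated genes fell in 21 of 31 cases and rose in 2 in WT, and fell in 20 in KO (camera adjusted p = 1.32e-05 and 2.47e-05; adjusted p = 0.39 and 0.297 with an estimated correlation; the same counts adjusted over the list alone). IFIT1 fell 5.2-fold and IFI6 3.05-fold in WT, and IFIT2 5.15-fold in WT and 7.78-fold in KO. The list was not called in the other 3 comparisons (0.469, 0.977 and 0.606). Glycolysis and hypoxia genes rose in 16 of 24 cases and fell in 4 in WT, and in 15 and 4 in KO (0.0135 and 0.00417; 0.37 and 0.297 with an estimated correlation; 16 and 4 in both adjusted over the list alone). They were lower in KO without 4-OHT in 2 of 24 cases (0.0045; 0.321; 6 adjusted over the list alone), and not called with 4-OHT or in the interaction (0.815 and 0.16).

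Mitochondrially encoded messages moved apart between the genotypes. Without 4-OHT 7 of 13 were higher in KO and with it 4 were lower (camera adjusted p = 5.77e-10 and 0.00301; adjusted p = 0.315 and 0.473 with an estimated correlation; 11 and 5 adjusted over the list alone). MT-ND6 and MT-ND5 were 1.6-fold and 1.47-fold higher in KO without 4-OHT. In the 4-OHT response 5 of 13 rose in WT (0.0388; 0.617; 5 adjusted over the list alone) and 10 fell in KO (0.00112; 0.297; 10), and 9 were lower in the interaction (1.16e-09; 0.247; 11). MT-CO1 measured 569 ± 113 and 628 ± 65 RPKM in WT and 877 ± 13 and 344 ± 25 in KO, and MT-ND4 fell 1.99-fold in KO. The WT call ended without the untreated library of clone 54 (0.209) or the treated one of clone 15 (0.184) with library size only (0.0772) and with fry (0.0696), and the call between genotypes with 4-OHT without WT clone 15 (0.0813) and with fry (0.109). Without WT clone 15, WT clone 54, KO clone 66 or KO clone 69 in that order, 11, 2, 0 and 0 members were higher in KO without 4-OHT and 0, 2, 1 and 0 lower with it. In the interaction 4 to 10 were lower with each library left out. Nuclear-encoded oxidative phosphorylation genes rose in 23 of 64 cases and fell in 3 in WT, and in 33 and 3 in KO (0.00192 and 0.00016; 0.528 and 0.297 with an estimated correlation; the same counts adjusted over the list alone). Without 4-OHT 3 were lower in KO (0.0232; 0.636; 2 adjusted over the list alone), a call that ended without WT clone 15 (0.942) or KO clone 66 (0.189), and the list was not called with 4-OHT or in the interaction (0.776 and 0.205).

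Lysosome genes fell in 15 of 31 cases and rose in 8 in WT, and fell in 20 and rose in 2 in KO (camera adjusted p = 0.0219 and 9.48e-06; adjusted p = 0.37 and 0.215 with an estimated correlation; 18 and 8, and 20 and 3, adjusted over the list alone). The lysosomal glucosidase GAA fell 3.69-fold in WT and 3.99-fold in KO, and prosaposin (PSAP) 1.94-fold and 2.34-fold. With 4-OHT 10 were lower and 2 higher in KO (0.000835; 0.299; 12 and 2 adjusted over the list alone), with GUSB 2-fold higher, and 7 were lower and 1 higher in the interaction (8.95e-06; 0.247; 11 and 1). Without 4-OHT 2 were higher in KO (0.0187; 0.325; 3). Integrated stress response genes rose in 14 of 30 cases and fell in 3 in KO (0.0227; 0.66; 14 and 3), a call that ended without the treated library of clone 69 (0.247), and were not called in WT or between genotypes with 4-OHT (0.43 and 0.428). Without 4-OHT 4 were lower and 1 higher in KO (0.000175; 0.585; 9 and 1), with DDIT4 3.1-fold and CHAC1 1.87-fold lower. Their interaction (0.0293; 0.72; 2 higher and 1 lower) lost its call without the untreated library of WT clone 15 (0.063), the treated one of WT clone 54 (0.112) or of KO clone 69 (0.346).

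Small-subunit ribosomal proteins rose in 8 of 32 cases in WT (camera adjusted p = 0.0282; adjusted p = 0.617 with an estimated correlation; 6 adjusted over the list alone), a call that ended without the untreated (0.18) or treated library of clone 54 (0.154) with library size only (0.0827) and with fry (0.0696). With 4-OHT, 3 of 32 small-subunit and 2 of 47 large-subunit members were higher in KO (0.000745 and 0.0122; 0.477 and 0.72; 0 and 0 adjusted over the list alone), as were 5 of 17 snoRNA host genes with 1 lower (0.0322; 0.459; 6 and 2). The large-subunit and host calls ended without WT clone 15 (0.0813 each), and the host call also without KO clone 66 (0.0582). With fry the small-subunit, large-subunit and host calls ended (0.0998, 0.284 and 0.0741). Fibroblast markers were higher in KO with 4-OHT in 3 of 13 cases (0.00586; 0.357; 3). Extracellular matrix genes were lower in KO without 4-OHT in 5 of 40 cases and higher in 2 (0.0214; 0.635; 9 and 4), a call that ended without WT clone 54 (0.154) or KO clone 69 (0.215). In the interaction, large-subunit proteins had 0 members called (0.0248; 0.72), and matrix genes had 7 higher and 2 lower (0.0489; 0.669; 9 and 3). The large-subunit call ended without the untreated (0.268) or treated library of WT clone 54 (0.122), or of KO clone 69 (0.0787 and 0.0544). The matrix call ended without the same libraries of WT clone 54 (0.151 and 0.122), the untreated one of KO clone 69 (0.17) or the treated one of KO clone 66 (0.302). The list median and the camera direction differed in sign, or the mean did, for host genes and 5q22 genes in the KO response, contractile, interferon-stimulated, 5q22 and fibroblast genes between KO and WT without 4-OHT, and RAS-MAPK output and epithelial genes in the interaction, none of which was called.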
